A study of Macaca fascicularis with 4 samples.

How the data were processed

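Droplet single-cell RNA sequencing of transcript 3′ ends was analysed for 4 libraries of cynomolgus monkey embryos, 1 each at embryonic day 24 (E24, Carnegie stage 11), E28 (stage 13), E31 (stage 14) and E37 (stage 18). Per the labels' protocols, tissue was dissociated with trypsin and EDTA and loaded for droplet capture; the protocol names both v2 chemistry and v3 kits, and which applied to which library is not given in the sources used here. Per the submitters' processing notes, Cell Ranger 2.1.0 made the count matrices, and the deposited values are raw UMI counts per gene and cell barcode, with barcodes already called as cells by the authors. The genome build and annotation are not given in the sources used here. The E24 label names more than 1 embryo, but its barcodes carry a single suffix, so the library was taken as 1 sample. Mouse samples were not analysed here.

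Each table held 26223 gene rows. A row with a blank name (1 row) held 0 UMIs, a share of 0%, in every library. Of the rows, 9499 carried LOC identifiers, of which 3867 were found in the reference name table and 673 were given a symbol. These LOC rows held 6.05%, 6.50%, 6.17% and 6.40% of UMIs at E24, E28, E31 and E37. No mitochondrial gene is named in the tables, so no limit on mitochondrial UMIs could be set. CYP11A1, SRY, HSD3B1, HBG1, HBG2, HBD, HBA1, HBA2, HSPA1A, HSPA1B, HOXD12, UNCX, MYMK, SOX1 and PF4 are not among the gene names, and nothing is stated about them.

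The libraries held 10639, 5028, 6661 and 5298 barcodes, with medians of 9990, 11391, 9766 and 6672.5 UMIs and of 3077, 3485, 3135 and 2462 genes. UMIs per barcode ran from 3736 to 57569, 3685 to 59276, 3446 to 58407 and 2259 to 37802. Barcodes with under 500 genes (0, 0, 0 and 5) were left out. Scrublet, run in scanpy 1.11.5, called 2, 78, 18 and 16 doublets, or 0.0188%, 1.55%, 0.270% and 0.302%, and these were removed. Under 0.5% in E24, E31 and E37 is too low for libraries of this size, so the call had not worked there, and an alternative at an expected rate of 0.8% per 1000 barcodes, removing 906, 202, 355 and 225 cells by Scrublet score, was added after the data were seen. The cells kept were 10637, 4950, 6643 and 5277. A gene without a UMI in a library lies below 2.60e-06%, 4.80e-06%, 4.15e-06% and 7.45e-06% of its UMIs, the limit set by 3 counts.

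Each library was normalized to 10000 UMIs per cell, log-transformed and scaled with values limited to 10, using 2000 variable genes found in at least 3 cells, with all outcome-list genes left out. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1 with seed 0 (igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, Python 3.11.15; figures with matplotlib 3.10.9). They were named from 26 marker classes fixed before the data were examined. A marker counted as high at 2-fold or more over the median cluster and in at least 5% of cells. Leading genes were the 10 with the highest ratio among genes in at least 20% of cells, with a prior of 5 CPM. A name asked for at least 3 high markers, a marker among the leading genes and 40% of markers high, or 75% without a leading marker, and was not given at a tie, where another class had more markers among the leading genes or where the share of high markers of another class was at least 40 percentage points above, nor without a leading marker at a median depth under 33.3% of that of the library. These thresholds were set after the data were seen. Every name is a statement of marker levels, written as "like".

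Within a class UMIs were summed over cells and scaled to the class total as CPM. Ratios have exact conditional binomial 95% intervals, levels exact Poisson intervals and shares of cells exact binomial intervals. All are counting error within 1 library. Where a sum was 0, a bound from 3 counts was used, and list medians and alternatives used a pseudocount of 0.5 UMIs. Cells with a UMI were counted as they are and after thinning each cell to 2000 UMIs. Whole-library gene levels leave out cells with germ cell markers. No tests were run, since no stage has a second library.

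Comparisons were made between neighbouring stages within each class named in both with at least 50 cells, and between gonadal-somatic-like cells at E37 and coelomic-epithelium-like cells at E31. Erythroid-like cells numbered 48 at E28 and at E31 and were reported under a comparison of their own planned beforehand. The comparisons of cluster 19 were chosen after its values were seen. In each, up to 8 genes per direction were named, by the interval bound nearest 1, among genes with a symbol and at least 50 UMIs in the higher class. Ribosomal, LOC and class-marker genes were left out, and globins were left out except in erythroid-like cells. All are given for the coelomic, gonadal, intermediate mesoderm and cluster 19 comparisons and the first 2 per direction for other classes. To these were added GATA4, NR5A1, LHX9, EMX2, WT1, OSR1, PAX2, PAX8, ALDH1A2, CDH1, KRT8, KRT18, VIM and PDGFRA, chosen before the data were examined, in the coelomic and gonadal comparisons, and list members with the bound farthest from 1. List members are all named where a count is 5 or lower in the main comparisons.

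The 18 gene lists, fixed before the data were examined, were gonadal regulators, supporting lineage and sex determination, steroidogenesis, epithelial, mesenchymal, nephrogenic mesoderm, BMP and TGF-beta, WNT, hedgehog, retinoic acid, NOTCH, cell cycle, globins, germ cell pluripotency, germ cell meiosis, dissociation stress, hypoxia and glycolysis, and HOX genes. A member was measured with 20 UMIs in either class and counted as higher or lower at 2-fold with its interval beyond 1; markers of the compared class were left out. Lists with fewer than 5 measured members have no median. Medians were placed among those of 10000 random lists matched on level. HBQ1 was added to the named globins after the data were seen. Germ-cell-like cells were those with UMIs of at least 3 of 11 markers. Other classes print only some lists, picked after the values were seen, with the stress list always among them.

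The alternatives planned before the data were examined were at least 1000 genes per cell, called doublets kept, Leiden resolution 2, outcome genes kept among the variable genes, the libraries clustered together without integration, TMM factors (edgeR 4.0.16 in R 4.3.3), means of CPM over cells, 50 UMIs for a measured member, members counted at 1.5-fold, 2 or 4 germ cell markers, and cells not thinned or thinned to 4000 UMIs. The TMM factors shifted log2 ratios by over 0.1 for E28 over E24 in intermediate-mesoderm-like (−0.18), nephric (−0.14), glia-like (−0.17), smooth-muscle-like (−0.12) and somite-like cells (−0.14), in erythroid-like cells (0.36, 0.13 and 0.38), in macrophage-like cells (0.18) and for E37 over E31 in smooth-muscle-like cells (−0.12).

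The comparison code was tested on simulated data at the depth of coelomic-epithelium-like cells at E31 and E28, with 200 of 11996 genes made different, 50 at each size. The interval held the true ratio for 95.4% of 11796 unchanged genes, and 52 of these (0.441%) were counted as different. Of the genes made different, 2% were counted at 1.5-fold, 44% at 2-fold and 100% at 4-fold and 8-fold. Of 100 random lists 7 fell outside the central 95% of percentiles, and 12 genes made higher stood at percentile 100. Some genes are not reported here.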

Results

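Gonadal somatic cells, the cells of the ovary and testis other than germ cells, form on the urogenital ridge beside the mesonephros and beneath the coelomic epithelium that lines the body cavity. The series title names their embryonic origin as its subject. Tissue from cynomolgus monkey (Macaca fascicularis) embryos was dissociated and profiled by droplet single-cell RNA sequencing of transcript 3′ ends, with 1 library at each of 4 stages: embryonic day 24 (E24, Carnegie stage 11), E28 (stage 13), E31 (stage 14) and E37 (stage 18). The libraries held 10639, 5028, 6661 and 5298 cell barcodes in that order, 27626 in all. Their totals were 115332663, 62477350, 72233442 and 40243286 unique molecular identifiers (UMIs). The median barcode held 9990, 11391, 9766 and 6672.5 UMIs. The tissue taken differed: most of the trunk at E24, the urogenital ridge with mesonephros, coelomic epithelium and nearby mesentery at E28 and E31, and mainly the gonadal ridge with some mesonephros, presumed adrenal tissue and mesentery at E37. With 1 library per stage no difference below has a replicate check, so each is a difference between libraries, and the 95% intervals cover counting error only.

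After filtering, 10637, 4950, 6643 and 5277 cells remained, and each library was clustered alone into 29, 22, 23 and 27 clusters, numbered within its library. Clusters were named only from markers fixed before the data were examined. Because the dissections differed, the shares of cells reflect the tissue taken as well as the embryo. Coelomic-epithelium-like cells made up 11.98% of cells at E28 (593 cells, 11.1% to 12.9%, clusters 3 and 4) and 13.3% at E31 (886 cells, 12.5% to 14.2%, clusters 1 and 14), and no cluster met the naming rule for this class at E24 or E37. Gonadal-somatic-like cells were named at E37 alone, with 516 cells or 9.78% (8.99% to 10.6%, clusters 10 and 12). Intermediate-mesoderm-like cells, the class of the kidney precursors, were 3.51% of cells at E24 (373 cells, cluster 7), 20.2% at E28 (1001 cells, clusters 0, 18 and 19), 16.3% at E31 (1084 cells, clusters 0, 6 and 12) and 4.34% at E37 (229 cells, cluster 18).

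Nephric-epithelium-like cells held 1.31%, 6.28%, 6.68% and 2.12% of cells at E24, E28, E31 and E37. Podocyte-like cells, which form the filter of the kidney, held 9.88% at E28, 7.03% at E31 and 0.322% at E37. Endothelium-like cells were 2.84%, 4.28%, 4.53% and 3.68% across the 4 stages, and smooth-muscle-like cells 6.33%, 3.76%, 3.27% and 4.605%. Neural-crest-like or glia-like cells held 1.30%, 2.38%, 2.95% and 7.75%. Erythroid-like cells held 0.931%, 0.970%, 0.723% and 2.103%, and macrophage-like cells 0.367%, 0.929%, 0.783% and 1.76%. Somite-like or sclerotome-like cells held 12.8% at E24, 6.34% at E28 and 5.95% at E31. E24, which took in most of the trunk, also held splanchnic-mesenchyme-like (12.6%), neural-tube-like (11.02%), limb-mesenchyme-like (10.5%), neuromesodermal-like (8.93%), surface-ectoderm-like (5.50%) and notochord-like cells (2.35%). E37 held sympathoadrenal-like (2.01%) and splanchnic-mesenchyme-like cells (2.14%). The naming thresholds were set after the data were seen and left 18.6%, 32.8%, 36.6% and 59.03% of cells unnamed at E24, E28, E31 and E37. The shares of the coelomic and gonadal classes depended on the clustering: the gonadal class held 4.89% at a Leiden resolution of 2, 4.98% with the outcome genes kept among the clustering genes and 0.114% with the libraries clustered together.

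**Figure D1:**
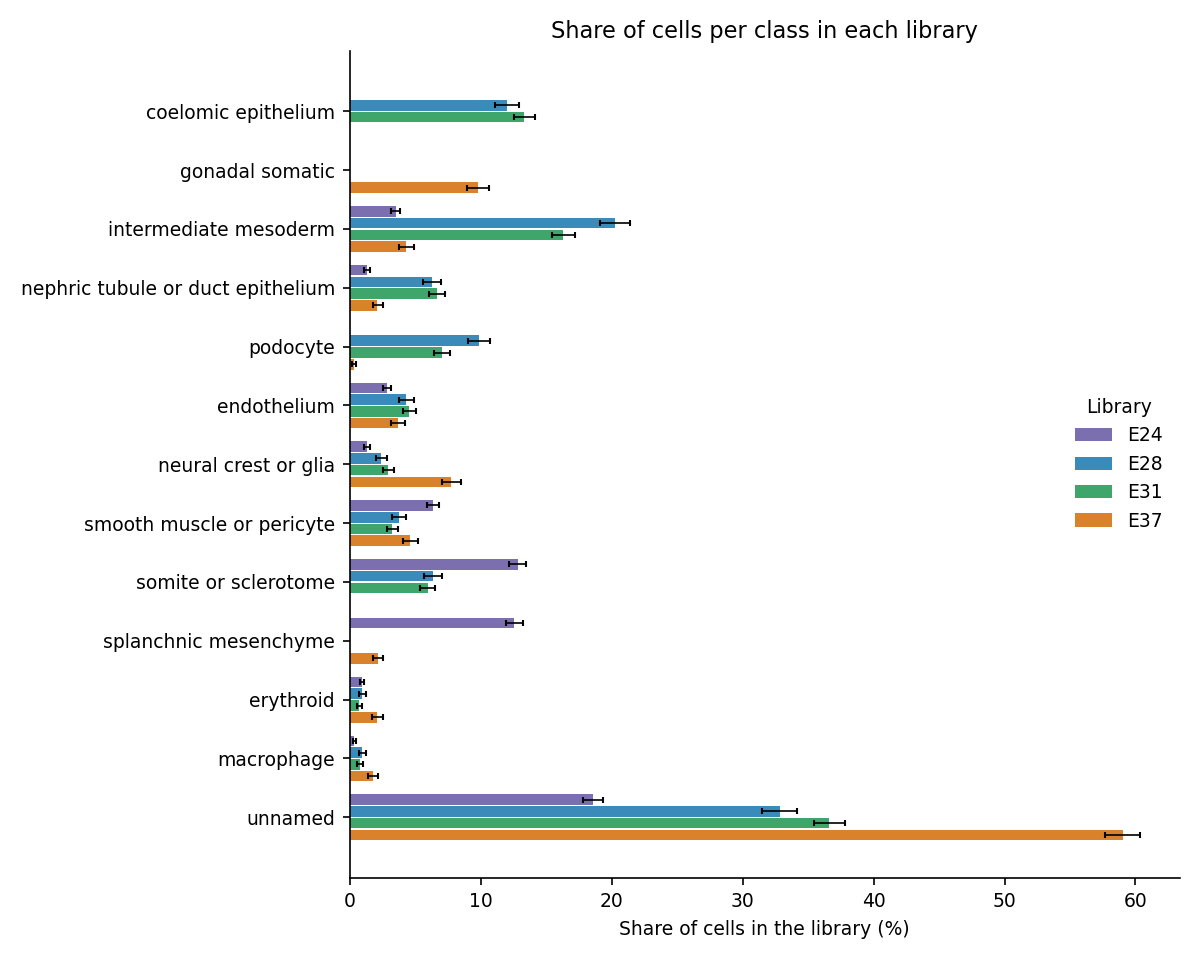
Share of cells (horizontal axis, percent) in each named class, and unnamed, in the E24, E28, E31 and E37 libraries, with exact 95% binomial intervals as error bars. Coelomic-epithelium-like cells appear at E28 (11.98%) and E31 (13.3%), gonadal-somatic-like cells at E37 (9.78%), and the unnamed share is 59.03% at E37.

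The first question was where and when the regulators of the gonadal ridge were detected, counted over whole libraries so that no class name enters. GATA4, a transcription factor needed for the gonadal ridge to form in mice, stood at 3.45, 0.511, 0.446 and 12.3 CPM at E24, E28, E31 and E37, where 10 CPM is 0.001% of UMIs. At E28 no cluster exceeded 3.02 CPM and at E31 none exceeded 2.64 CPM, whereas 6 of the 27 clusters at E37 reached 20 CPM. LHX9, another gonadal transcription factor, stood at 0.148, 3.15, 1.19 and 32.9 CPM, with 282 CPM in cluster 12, 199 in cluster 19, 147 in cluster 10 and 109 in cluster 2 at E37. GATA4 in the same E37 clusters stood at 40.4, 89.6, 68.1 and 21.3 CPM, and cluster 11 held 108 CPM. At E24 the highest GATA4 level, 21.5 CPM, lay in cluster 22, an unnamed cluster led by KYNU and FGB. LHX2 stood at 6.22 CPM at E37, with 162 CPM in cluster 11.

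EMX2 and WT1, which act in both kidney and gonad development, were at their highest before E37: EMX2 at 143 and 119 CPM at E28 and E31 against 20.1 at E37, and WT1 at 171 and 149.6 CPM against 79.2. The kidney genes PAX8 (115, 87.3 and 4.01 CPM at E28, E31 and E37), LHX1 (165, 159 and 4.29 CPM) and PAX2 (21.99, 11.7 and 1.70 CPM) were lower at E37 than at E28 and E31. The E37 dissection was mainly gonadal ridge. NR5A1, the nuclear receptor of steroidogenic and gonadal cells, had 1, 6, 5 and 7 UMIs in the 4 libraries, and all 7 at E37 lay in cluster 9. The annotation used is not given in the sources used here, so these counts are not read as absence of NR5A1 expression. FOXL2, a gene of the ovarian supporting lineage, had 7, 4, 1 and 0 UMIs. These values do not separate stage from the tissue taken.

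Coelomic-epithelium-like cells were compared between E31 and E28, the pair with the same dissection, to see whether this epithelium differed before gonadal cells were found. Immediate early genes, which respond within minutes to stimuli and to tissue handling, were lower at E31: EGR1 by 10.2-fold (8.80 to 11.9, 19.5 against 199 CPM), JUNB by 8.34-fold (6.25 to 11.3) and FOS by 6.66-fold (6.12 to 7.26, 63.4 against 423 CPM). LHX9 was 2.89-fold lower at E31 (2.16 to 3.88, 6.82 against 19.7 CPM) and PAX8 1.65-fold lower (1.45 to 1.87, 42.2 against 69.5 CPM), while OSR1, an early marker of intermediate mesoderm, was 1.95-fold higher (1.58 to 2.43, 30.1 against 15.4 CPM). The epithelial keratins KRT8 (580.1 against 552 CPM) and KRT18 (349 against 359 CPM) stood close in both libraries. VIM, an intermediate filament of mesenchyme, was 1.74-fold lower at E31 (605 against 1054 CPM).

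Of the genes named by size, STYXL1 (7.93-fold, 5.00 to 13.3), MRPL54 (5.64-fold), CBY3 (5.31-fold), SYCP3 (6.22-fold, 3.10 to 14.1), UCP2 (4.13-fold), MATN3 (3.89-fold), IGLL5 (3.20-fold) and TYW3 (2.73-fold, 2.34 to 3.20) were higher at E31. EGR3 (33.5-fold, 8.81 to 284, 2 UMIs at E31), HPGD (8.42-fold), FOSB (6.19-fold), ATF3 (4.66-fold) and DNLZ (4.497-fold) were lower beside EGR1, JUNB and FOS. At E31, STYXL1, MRPL54 and CBY3 were higher and DNLZ and FOSB lower in all 8 classes that measured them. They are not specific to this epithelium. PAX2 had 17 UMIs at E31 and 40 at E28, GATA4 12 and 18, NR5A1 1 and 2, and CDH1, the epithelial cadherin, 1 and 0. GATA4 was 1.93-fold lower (0.880 to 4.39), a difference not detectable at this depth. ALDH1A2, which makes retinoic acid, stood at 270.5 against 287 CPM, PDGFRA at 12.7 against 12.5, and the class marker WT1 at 144 against 171 CPM. EMX2 stood at 126 against 143 CPM.

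Among the fixed gene lists in this comparison, a member counted as higher or lower at 2-fold or more. In the dissociation stress list 7 of 10 measured genes were lower and none higher, with a median log2 ratio of −2.13 (−3.05 to −0.16 over members). The epithelial list had 0 of 11 apart with a median of −0.01, and the mesenchymal list 1 of 23 lower (DCN, 2.52-fold) with a median of −0.13. The nephrogenic list had 1 of 10 lower (PAX2) and a median of 0.39 (−0.72 to 0.91). Gonadal regulators had LHX2 higher (15.5-fold, 2.49 to 644, 1 UMI at E28) and LHX9 lower among 14, with a median of 0.05. The supporting lineage list had PTGDS higher (2.33-fold) and WNT4 lower (2.77-fold) among 12, with a median of −0.03.

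Signalling lists stood near 0 between E31 and E28 in this epithelium. The BMP list had BMPR1B higher (2.07-fold) and SMAD6 lower (2.04-fold) of 18 with a median of −0.17. The WNT list had WNT5A higher (2.03-fold) and WNT4 lower of 12. NOTCH had LFNG lower (2.07-fold) of 8 with a median of −0.33, and the pluripotency list had KLF4 lower (3.19-fold) of 8 with a median of −0.07. No member passed 2-fold in the steroidogenesis (6 measured, median 0.04), hedgehog (6, −0.07), retinoic acid (13, 0.06), cell cycle (18, 0.10), hypoxia and glycolysis (11, −0.06) and HOX lists (31, 0.11). The meiosis list had under 5 measured members and no median. Of the 30 named genes 8 shifted by over 1.5 times under some alternative. With doublets removed at the expected rate, an alternative chosen after seeing the data, the class kept 7.06% of E31 cells, the cell cycle median became −2.45, the log2 ratios of UCP2 and MATN3 became 0.93 and 0.41 from 2.02 and 1.93, and ALDH1A2 turned to 0.11. Clustering the libraries together gave EGR3 −3.26 in place of −4.76.

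**Figure D2:**
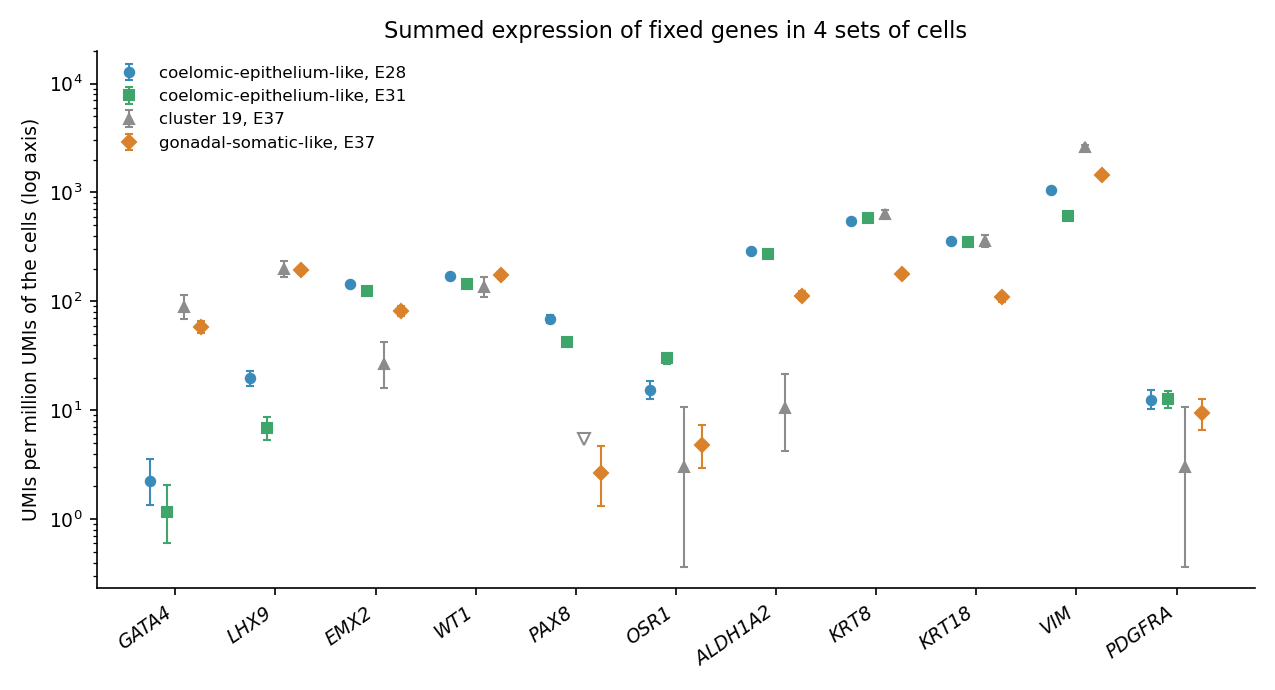
Levels of 11 genes fixed beforehand (vertical axis, CPM of the class total, log scale) in coelomic-epithelium-like cells at E28 and E31, cluster 19 at E37 and gonadal-somatic-like cells at E37, with exact 95% Poisson intervals and an open triangle at the upper bound where no UMI was found (PAX8 in cluster 19). GATA4 stands at 89.6 CPM in cluster 19 and 58.7 in gonadal-somatic-like cells against 1.17 in the E31 epithelium, while KRT8 in cluster 19 (632 CPM) stands near the E31 epithelium (580.1 CPM).

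Gonadal-somatic-like cells at E37 were compared with coelomic-epithelium-like cells at E31, their presumed source. They differ in stage, dissection and depth as well as type. No coelomic class was named at E37, so no comparison within that library was possible. DCN, a collagen-binding proteoglycan, was 52.4-fold higher in the gonadal class (44.6 to 61.9, 791 against 15.1 CPM) and VIM 2.40-fold higher (2.32 to 2.49, 1452 against 605 CPM). DCN was also higher at E37 than at E31 in all 6 classes named in both libraries that measured it, so it is not specific to gonadal cells. Epithelial and kidney genes were lower: KRT8 by 3.26-fold (178 against 580.1 CPM), KRT18 by 3.20-fold, PAX8 by 16.003-fold (2.64 against 42.2 CPM) and OSR1 by 6.28-fold. ALDH1A2 was 2.39-fold lower, and WT1 was 1.21-fold higher (174 against 144 CPM).

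GATA4 (50.2-fold), LHX9 (28.3-fold) and EMX2 (1.53-fold lower) are markers by which the gonadal class was named, so their values describe the naming. NR0B1, another of its markers, was lower, at 37.4 against 228 CPM. Genes named by size and higher in the gonadal class were CXCL11 (at least 107-fold), TMEM215 (at least 55.8-fold) and FREM3 (at least 49.2-fold), each without a UMI in the E31 class and bounded by 3 counts over its total. SH3GL2 (67.2-fold, 40.3 to 121), GAP43 (59.5-fold, 38.1 to 98.3), LGALS3BP (189-fold, 33.0 to 7577, 1 UMI at E31) and COL9A3 (38.2-fold, 28.02 to 53.2) were also higher. Lower were ENO3, a muscle enolase (43.5-fold, 30.9 to 63.3), the kidney regulator LHX1 (at least 31.8-fold), NPPB (130.1-fold, 23.2 to 5154, 1 UMI), EDN3 (27.0-fold), LIN28A, an RNA-binding protein of early embryonic cells (28.6-fold), and PITX1 (95.1-fold, 16.9 to 3773, 1 UMI). ENO3 and LIN28A were also lower at E37 in all 7 and all 5 shared classes that measured them. They are not specific to gonadal cells. PAX2 was at least 2.30-fold lower, PDGFRA stood at 9.35 against 12.7 CPM, and NR5A1 and CDH1 each had 0 UMIs against 1.

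The epithelial list had 7 of 11 measured genes lower and none higher in the gonadal class, with a median log2 ratio of −1.67, among them LAMA1 (11.8-fold), CDH3 (6.03-fold) and PKP2 (5.27-fold). The mesenchymal list had 6 of 23 higher and none lower (median 0.42), among them DCN, TCF21 (12.5-fold), CDH11 (3.30-fold) and TWIST1 (2.90-fold). The nephrogenic list had 6 of 9 lower and none higher (median −2.62, −4.55 to 0.19), among them LHX1, EYA1 (27.2-fold, 9.19 to 133, 3 UMIs), SALL1 (27.6-fold, 7.51 to 231, 2 UMIs) and PAX8. In the supporting lineage list 5 of 11 were higher, namely SOX9 (4.43-fold), GADD45G (4.44-fold), BMP2 (3.25-fold), WNT4 (3.03-fold) and FGF9 (2.22-fold), and IRX3 was lower (47.6-fold, 8.37 to 1895, 1 UMI), with a median of 0.98. Gonadal regulators other than the class markers had TCF21 and LHX2 (13.3-fold) higher and SIX4 (2.26-fold) and CITED2 (2.004-fold) among the lower of 11, with a median of −0.46. The HOX list had 19 of 31 lower and none higher (median −1.19, −1.44 to −0.61), with HOXB9 (32.2-fold) and HOXB8 (28.8-fold) foremost. HOXB8 was also lower at E37 in all 5 shared classes that measured it and HOXB9 in 4 of 5. They are not specific to gonadal cells. The genes of HOX paralogue group 11 together stood at 1.02-fold.

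Signalling lists differed member by member between these 2 classes. In the BMP list INHBA (17.8-fold), TGFB2 (12.4-fold), BMP2 and SMAD6 (2.52-fold) were higher and BMP7 (8.13-fold), GREM1 (7.52-fold, 1.94 to 64.4, 2 UMIs) and BMPR1B (4.88-fold) lower among 19, with a median of 0.59. In the WNT list SFRP1 (3.63-fold), RSPO3 (2.39-fold), WNT4 and WNT2B (2.01-fold) were higher and NKD1 (5.49-fold) lower among 12 (median 0.39). The retinoic acid list had CRABP1 higher (2.23-fold) and 5 of 12 lower, namely RDH10 (7.55-fold), CYP26B1 (at least 7.32-fold), CRABP2 (7.12-fold), ALDH1A1 (5.77-fold) and ALDH1A2, with a median of −0.86. NOTCH had JAG1 (3.28-fold) and HEYL (2.12-fold) lower of 7 (median −0.24), hedgehog had HHIP higher (7.38-fold) of 7 (median 0.25), and hypoxia and glycolysis had VEGFA higher (2.22-fold) of 11 (median 0.11). The pluripotency list had KLF4 (5.41-fold) and UTF1 (61.5-fold, 10.1 to 2525, 1 UMI) higher and LIN28A lower of 9 (median 0.06). No steroidogenesis member of 6 (median 0.13) and no cell cycle member of 18 (median 0.32) passed 2-fold. The stress list had 8 of 10 higher (median 3.41), with JUNB at 26.0-fold and FOS at 12.3-fold.

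This comparison moved with the choice of clustering genes. With the outcome genes kept among them, the mesenchymal, BMP and cell cycle medians turned to −0.16, −0.03 and −0.72, EMX2 turned to a log2 ratio of 0.49, the retinoic acid median became −1.49, and DCN, PAX8 and ALDH1A2 became 4.44, −2.67 and −0.23 from 5.71, −3.94 and −1.26, while WT1 became 0.92 and KRT18 −2.89. Removing doublets at the expected rate gave a cell cycle median of 2.59, a nephrogenic median of −3.70, ENO3 at −4.63, LHX1 at −4.33 and PITX1 at −3.10. In all 21 of the 30 named genes shifted by over 1.5 times under some alternative.

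**Figure D3:**
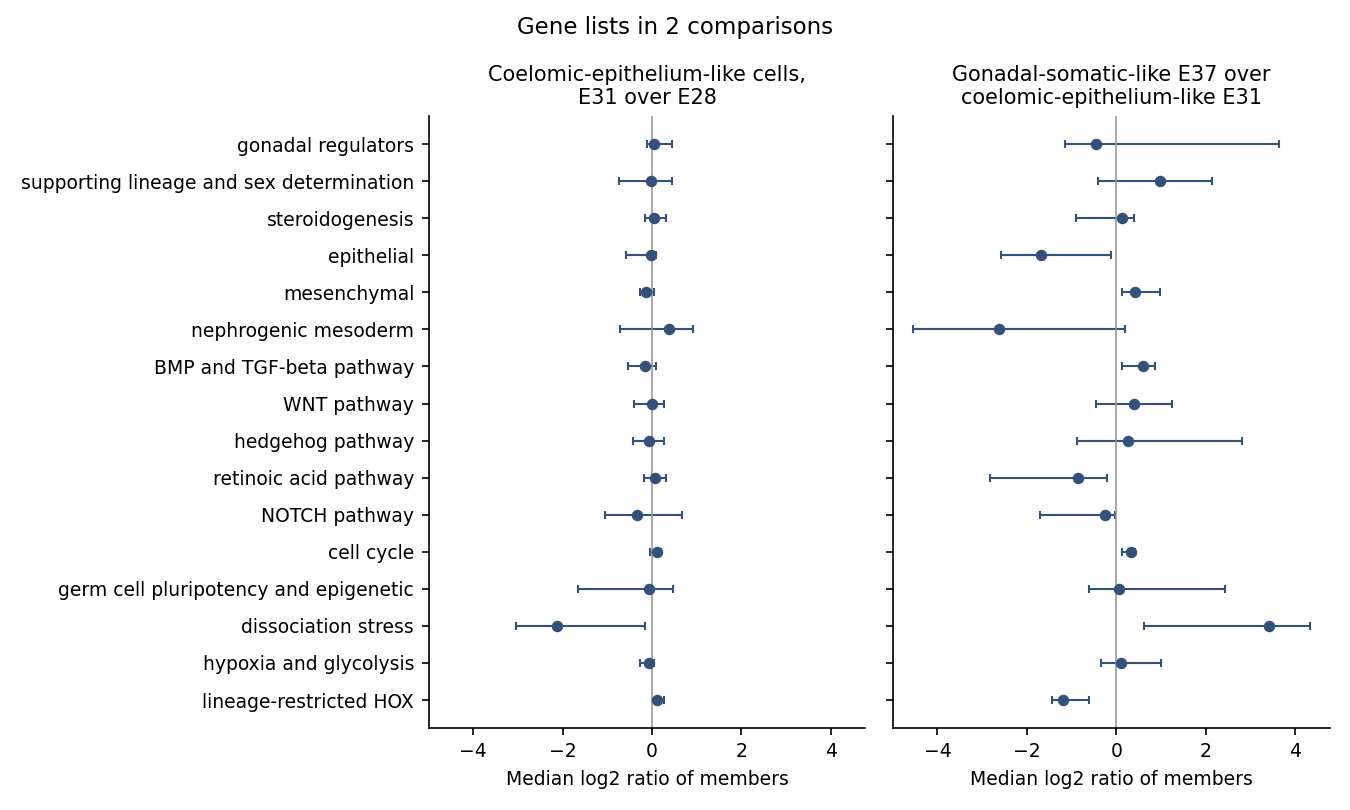
Median log2 ratio (horizontal axis) of 16 fixed gene lists in coelomic-epithelium-like cells at E31 over E28 and in gonadal-somatic-like cells at E37 over coelomic-epithelium-like cells at E31, with 95% intervals over list members as bars. The stress list stands at −2.13 in the former and 3.41 in the latter, and the nephrogenic list at −2.62 in the latter. Under another choice of clustering genes the mesenchymal, BMP and cell cycle medians of the latter comparison turn to −0.16, −0.03 and −0.72.

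Cluster 19 at E37, with 78 cells, stayed unnamed because more markers of another class led it; it was singled out after its values were seen, and its values were computed under the main settings only. It paired keratins at the level of the E31 epithelium with higher GATA4 and LHX9: against coelomic-epithelium-like cells at E31, KRT8 stood at 1.09-fold (0.984 to 1.20) and KRT18 at 1.02-fold, while GATA4 was 76.6-fold higher (40.8 to 156) and LHX9 29.1-fold higher (21.6 to 39.5). VIM was 4.29-fold higher and EMX2 4.67-fold lower, and WT1 stood at 0.946-fold. Of 15 gonadal regulators, GATA4, LHX9, LHX2 and TCF21 were higher and EMX2, NR0B1 (3.63-fold), CBX2 and INSR among the lower (median −0.44). CXCL14 (332-fold, 109 to 1652, 3 UMIs at E31), DCN (116-fold), GAP43 (120.3-fold), SH3GL2 (58.2-fold), NFIA (45.6-fold), MATN2 (46.6-fold) and HLX (35.7-fold) were higher. DCN and NFIA were also higher at E37 than at E31 in all 6 and all 5 classes named in both libraries that measured them. ENO3, lower in cluster 19 as given below, was also lower in all 7 such classes. These 3 genes are therefore not specific to cluster 19.

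Division genes were lower in cluster 19 than in the E31 epithelium, with MKI67 at 8.96 CPM (6 UMIs). The 18 listed cell cycle genes were left out of the clustering, but other division genes, such as CDC20, ASPM and CDCA3, were not. The clustering may therefore partly set the differences in division given here. The cell cycle list had 16 of 18 lower than in the E31 epithelium (median −3.33), and UBE2C (62.5-fold, 17.3 to 516, 2 UMIs), CDC20 (37.0-fold, 12.6 to 180, 3 UMIs), ASPM (35.05-fold, 11.97 to 170.1, 3 UMIs), CDCA3 (63.3-fold, 11.3 to 2503, 1 UMI) and SGOL2 (at least 16.1-fold) led the lower genes with ENO3 (57.6-fold), MOXD1 (75.1-fold, 13.5 to 2970, 1 UMI) and ALDH1A2 (25.9-fold, 12.5 to 64.4). The HOX list had 21 of 31 lower (median −1.88), the nephrogenic list 6 of 9 lower (median −3.36, or −2.13 with genes at 0 UMIs set to their bounds) and the retinoic acid list 6 of 12 lower (−2.05, or −1.04 at the bounds). The mesenchymal list had 7 higher and 2 lower of 23 (PDGFRA 4.24-fold, 1.15 to 35.4, 2 UMIs, and POSTN 3.365-fold; median 0.62), and the stress list 6 of 9 higher (2.65). Epithelial genes lower in cluster 19 were CLDN1 (20.1-fold, 3.58 to 796.5, 1 UMI), LAMA1, PKP2 and CDH3, of 11 (−0.57, or −0.38 at the bounds). The gonadal-somatic-like cells of the same library differed from cluster 19 in the reverse way on division, with 16 of 18 cell cycle genes higher (median 3.43), led by UBE2C (91.4-fold, 25.25 to 756, 2 UMIs), CDCA3 (79.1-fold, 14.1 to 3132, 1 UMI), CDC20 (45.0-fold, 15.3 to 219, 3 UMIs), ASPM (41.4-fold, 14.1 to 201, 3 UMIs), CCNA2 (39.1-fold, 13.3 to 190, 3 UMIs), SGOL2 (at least 21.99-fold), MXD3 (at least 15.6-fold) and KIAA0101 (19.8-fold).

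Within the E37 library, a comparison free of stage and dissection, the gonadal class also had lower KRT8 (3.55-fold, 3.14 to 4.01), KRT18 (3.26-fold), CXCL14 (4.82-fold), TAGLN (3.51-fold), SULF1 (3.43-fold), TNNI1 (2.87-fold), S100A10 (2.78-fold) and PODXL (2.68-fold) than cluster 19. ALDH1A2 was 10.8-fold higher (5.21 to 27.1) and EMX2 3.06-fold higher. LHX9 stood at 0.970-fold (0.807 to 1.17). The epithelial list had 4 of 8 lower (KRT8, KRT18, DSP and CDH3; median −1.02), the HOX list 7 of 24 higher (0.41, or 0.57 at the bounds) and the mesenchymal list POSTN (4.495-fold) and ZEB1 higher and DCN lower (2.21-fold) of 23 (0.09). No stress gene of 10 passed 2-fold (0.41). KRT8, KRT18 and CXCL14 are among the genes that lead cluster 19, which was singled out after its values were seen. CXCL14 could enter the clustering, so its difference may be partly set by it. KRT8 and KRT18, as outcome-list genes, were left out of the clustering.

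Shares of cells with a UMI were read against endothelium-like cells, a class outside the coelomic and gonadal lineages. LHX9 was found in 60.5% of gonadal-somatic-like cells (56.1% to 64.7%, median depth 7353.5 UMIs) against 0.515% of endothelium-like cells at E37 (depth 8549), and in 29.3% against 0% after each cell was thinned to 2000 UMIs. In coelomic-epithelium-like cells the shares were 18.9% at E28 and 6.21% at E31 (depths 12831 and 11108), or 3.88% and 1.24% thinned, against 0% and 0.332% of endothelium-like cells (depths 12870 and 10204). PAX8 was found in 46.5% and 30.02% of coelomic-epithelium-like cells at E28 and E31 and in 1.55% of the gonadal class, or 12.6%, 8.47% and 0.194% thinned, against 3.77%, 6.31% and 0% of endothelium-like cells. For GATA4 the E28 and E31 shares of 2.87% and 0.903% lay below the 3.30% and 1.66% in endothelium-like cells but above the 0.0999% and 0.185% in intermediate-mesoderm-like cells, whereas 31.8% of gonadal-somatic-like cells and 53.8% of cluster 19 held a UMI (10.7% and 12.8% thinned) against 2.58% of endothelium-like cells at E37. A share of 0 among the 194 endothelium-like cells at E37 has an exact interval up to 1.88%. No cell of these classes was below 2000 UMIs.

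Intermediate-mesoderm-like cells were followed over all 4 stages. Between E24 and E28 genes of posterior identity separated the libraries: HOX paralogue group 10 was 8.02-fold higher at E28 (6.28 to 10.4) and CDX2, a caudal regulator, was at least 189-fold lower. Dissection differed, so position along the body does too. MAL (at least 127-fold), FXYD2 (at least 21.01-fold), IL1R1 (at least 20.4-fold), BCL11A (127-fold, 22.7 to 5040.1, 1 UMI), CLDN5 (59.1-fold, 16.2 to 490, 2 UMIs), FOSB (at least 37.7-fold) and FOS (16.3-fold, 13.1 to 20.7) were higher. LUM (209-fold, 36.3 to 8397, 1 UMI), CLDN10 (19.4-fold), TNNC1 (12.5-fold), IL24 (11.5-fold), RELN (11.5-fold), IGFBP5 (9.95-fold) and IFI27 (7.86-fold) were lower.

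Of the lists in this E28 over E24 comparison, BMP had 7 of 19 higher and none lower (median 0.88), led by INHBA (14.2-fold, 2.42 to 572, 1 UMI), SMAD6 (7.04-fold, 2.31 to 34.98, 3 UMIs) and SMAD7 (3.53-fold). Epithelial genes higher were CLDN3 (34.7-fold, 6.09 to 1381, 1 UMI), CLDN7, CLDN1 (5.18-fold), CDH3 and DSP of 17 (0.62, or 0.70 with genes at 0 UMIs set to their bounds). NOTCH1, NOTCH3 and HEYL were higher of 11 NOTCH genes (0.65), and EMX2 (3.28-fold) and WT1 (2.61-fold) of 13 gonadal regulators (0.35). WT1, CDX2, FOSB and LUM differed likewise in every class that measured them. The supporting lineage list had WNT4 (11.7-fold), RSPO1 (3.82-fold), SOX9 and PTGDS higher and FGF9 and FST lower of 11 (0.80, or 0.88 at the bounds). The mesenchymal list had POSTN and FN1 higher and LUM, SNAI1, ZEB1, TWIST1 and COL3A1 lower of 21 (0.17). The retinoic acid list had ALDH1A1 (47.6-fold, 8.41 to 1892, 1 UMI) among the higher and STRA6 and CRABP2 lower of 10 (0.19), and WNT had WNT4 and RSPO1 higher and RSPO3 and WNT5A lower of 13 (−0.08). KLF4 and TET2 were higher and LIN28A lower of 8 pluripotency genes (0.38), NDRG1 and VEGFA higher and BNIP3 lower of 11 hypoxia genes (−0.28), and HOXA10, HOXC10, HOXD8, HOXD9 and HOXD10 were among the higher and HOXB1 among the lower of 30 HOX genes (−0.04). No member passed 2-fold in the cell cycle (0.23), steroidogenesis (0.50) and hedgehog (−0.26) lists, and 6 of 10 stress genes were higher (2.14, or 2.22 at the bounds). The median of all measured genes was 0.23 here, and TMM factors shifted this comparison by −0.18, so these medians are relative to it. With the outcome genes kept in clustering the BMP median was 0.30, the supporting lineage median 0.06 and the cell cycle median −0.22. Of the 16 named genes 14 shifted by over 1.5 times under some alternative without turning, for example CLDN5 (3.67 from 5.56 at a Leiden resolution of 2) and CLDN10 (−2.44 from −4.22 with the libraries clustered together).

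Between E28 and E31, with the same dissection, intermediate-mesoderm-like cells had at most 2 members apart in each fixed list other than the stress list. Higher at E31 were SYCP3 (13.5-fold, 5.92 to 37.9), RGS16 (9.45-fold), IFI27 (6.52-fold, 5.61 to 7.60), APOBEC3B (5.87-fold), STYXL1 (5.27-fold), SST (4.29-fold), SERPINB9 (3.97-fold) and MRPL54 (3.79-fold). Lower were EGR3 (15.1-fold), TNMD (13.2-fold), ALDH8A1 (12.5-fold), SIM1 (11.998-fold), ADAD2 (16.8-fold, 5.45 to 84.2, 3 UMIs), FOSB (8.34-fold), TMEM255B (7.62-fold) and EGR1 (4.91-fold). TMEM255B was lower in all 5 classes that measured it. The stress list had 6 of 10 lower and none higher (median −1.20). Lists with members apart were mesenchymal (TWIST1 2.45-fold higher, VIM 2.31-fold lower, of 20, median 0.16), BMP (TGFB2 3.19-fold and BMP2 2.01-fold lower of 19, −0.22), supporting lineage (BMP2 lower of 11, −0.32), epithelial (MARVELD2 3.33-fold lower of 18, −0.25), WNT (LGR5 3.40-fold lower of 13, −0.12), hedgehog (GLI1 2.03-fold higher of 6, 0.01) and pluripotency (KLF4 3.63-fold lower of 8, −0.09). No member was apart in the gonadal regulator (0.04), retinoic acid (0.22), NOTCH (−0.14), cell cycle (0.11), hypoxia (−0.29), steroidogenesis (0.06) and HOX (0.08) lists. SST turned to log2 ratios between −0.44 and −1.97 under 4 alternatives, SIM1 became −0.63 from −3.46 with the libraries clustered together, and the cell cycle median turned to −0.62 with called doublets kept.

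At E37 intermediate-mesoderm-like cells had higher posterior HOX and lower epithelial and NOTCH genes than at E31. HOXA11 was 141-fold higher (72.6 to 314), HOXD11 50.4-fold (28.6 to 95.7) and HOXD10 11.01-fold, and the HOX group 11 genes together were 99.8-fold higher (65.3 to 160) and group 10 6.98-fold (6.45 to 7.56), whereas groups 3 to 9 stood between 0.852-fold and 1.503-fold. Group 11 genes are needed for the permanent kidney, the metanephros, in mice. KRT18 (301-fold, 83.3 to 2487, 2 UMIs), KRT8 (105-fold, 45.0 to 324), CCND1 (45.7-fold, 28.5 to 78.5), the NOTCH target HES4 (at least 48.4-fold), EMX2 (174-fold, 31.2 to 6889, 1 UMI), MAL (at least 30.9-fold), CCL26 (171-fold, 58.6 to 832, 3 UMIs) and EGFL6 (72.5-fold, 24.8 to 352, 3 UMIs) were lower at E37. ELAVL2 (22.01-fold), PCSK1N (11.04-fold), TMEM121 (10.2-fold), RSPO3 (9.53-fold) and PTGER2 (9.55-fold) were higher.

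The NOTCH list had 7 of 10 lower and none higher at E37 (median −2.96, or −2.67 with genes at 0 UMIs set to their bounds), among them JAG1 (22.5-fold), HEY1 (18.2-fold) and NOTCH2 (4.74-fold). The epithelial list had 9 lower and CLDN1 higher of 15 (median −1.500, or −1.517 at the bounds). The supporting lineage list had WNT4 (24.8-fold, 4.39 to 984, 1 UMI), BMP2, SOX8, IRX3 and FGF9 lower and GADD45G (4.73-fold) and FST (3.04-fold) higher of 11 (−0.99, or −1.20 at the bounds). BMP2, BMP4, GREM1 and TGFBR2 were lower of 18 BMP genes (−0.21, or −0.32 at the bounds). HOX had 10 higher and HOXC5, HOXB8, HOXB1 and HOXC9 lower of 33 (0.38). DCN (20.3-fold), ZEB1 (4.31-fold), POSTN, VIM and COL6A3 were higher and FN1 and CDH2 lower of 21 mesenchymal genes (0.20), and RDH10, DHRS3 and RARB higher and ALDH1A1 lower of 10 retinoic acid genes (0.40). RSPO3 was higher and WNT4, SFRP2 (14.4-fold) and SFRP1 lower of 12 WNT genes (−0.50), BNIP3 higher and NDRG1 and VEGFA (4.73-fold) lower of 11 hypoxia genes (0.45), and KLF4 higher and LIN28A lower of 8 pluripotency genes (−0.13). Gonadal regulators had EMX2 lower of 13 (−0.15), steroidogenesis SCARB1 higher (3.24-fold) of 6 (−0.06) and hedgehog GLI2 higher (2.34-fold) of 6 (0.20), no cell cycle gene passed 2-fold (−0.03, or 0.71 with called doublets kept), and 7 of 10 stress genes were higher (1.502). LHX1 (0 at E37, 208 CPM at E31), PAX8 (51.2, 198) and OSR1 (83.6, 16.8) differed, as did dissection, so 1 population is not assumed. The NOTCH median was −2.19 with called doublets kept, and HOXA11 was 6.43 in place of 7.07. Of 16 named genes 9 shifted by over 1.5 times without turning.

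Nephric-epithelium-like cells, the class of kidney tubules and ducts, were compared between E28 (311 cells) and E24 (139 cells). FXYD2, a sodium pump subunit of the kidney, was at least 406-fold higher at E28 and LGALS2 at least 136-fold. WT1 (at least 42.3-fold) and TCF21 (23.2-fold, 7.80 to 114, 3 UMIs), genes of podocytes and mesenchyme picked after their values were seen, were higher too. TFAP2A was 1019.7-fold lower (182 to 40370, 1 UMI) and PPP2R2B at least 154-fold lower. The NOTCH list had 7 of 8 higher (median 2.44), among them HEY1 (8.60-fold) and LFNG (9.77-fold), and 7 of 9 stress genes were higher (2.66, or 2.76 at the bounds). With the libraries clustered together TFAP2A stood at a log2 ratio of −2.35 in place of −9.41 and PPP2R2B at −5.01 in place of −9.85. From E28 to E31 (444 cells) ANKRD30B (55.9-fold, 9.69 to 2238, 1 UMI) and IFI27 (12.5-fold) were higher and NTS, the neurotensin gene (102-fold, 49.2 to 255), and ETNPPL (49.9-fold, 13.4 to 419, 2 UMIs) lower. IFI27 was higher in every other class that measured it too. The mesenchymal list had TCF21 (3.33-fold), PDGFRB (2.55-fold), CDH11 and COL1A1 higher of 14 (0.59), WT1 was 2.58-fold higher beside TCF21, and 5 of 9 stress genes were lower (−1.47). At a Leiden resolution of 2 that mesenchymal median was −0.02 and at 1000 genes per cell 1.54. All 4 named genes shifted by over 1.5 times under some alternative without turning, ANKRD30B to 4.12 from 5.23 and ETNPPL to −3.63 from −5.33 at a resolution of 2, and IFI27 to 2.20 from 3.60 and NTS to −5.55 from −6.57 with the libraries clustered together.

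From E31 to E37 (112 cells, cluster 13) nephric-epithelium-like cells differed on several lists. The kidney gene PAX8 stood at 21.6 against 233 CPM, while VIM stood at 2315 against 147 and ALDH1A2 at 243 against 59.2 CPM, so the differences are not read as those of nephric epithelium alone. DCN was 2402-fold higher (429 to 95040, 1 UMI at E31) and CXCL10 at least 219.6-fold higher, and CCL26 (at least 34.2-fold) and SFRP2 (23.4-fold, 17.6 to 31.9) were lower. The mesenchymal list had 15 higher and TCF21, ZEB2, CDH2 and FN1 lower of 20 (median 2.71), the epithelial list 6 of 14 higher and none lower (0.33), the retinoic acid list 8 of 11 higher (2.04), the WNT list 7 higher and SFRP2 lower of 12 (1.28), hypoxia SLC2A1, BNIP3 and CA9 higher of 11 (0.42), NOTCH 6 of 8 lower (−2.75) and stress 9 of 10 higher (3.14). At a Leiden resolution of 2 the mesenchymal, WNT and retinoic acid medians were 0.26, 0.27 and 0.57, and DCN and CXCL10 stood at 5.98 and 6.61 in place of 10.65 and 10.37. Podocyte-like cells at E31 (467 cells, cluster 7) against E28 (489 cells, clusters 1 and 15) had higher ANKRD30B (14.6-fold) and ADRA1D (12.8-fold) and lower CXCL10 (17.4-fold) and PCP4 (11.1-fold, a log2 ratio of −2.63 in place of −3.45 with called doublets kept). In podocyte-like cells 7 of 10 stress genes were lower at E31 (−1.26).

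Endothelium-like cells at E28 (212 cells) against E24 (302 cells) had higher MADCAM1, an adhesion molecule of vessels (13.9-fold, 8.18 to 25.3), and NT5E (8.68-fold). The hypoxia and glycolysis list had 7 of 12 lower at E28 (median −1.06), among them SLC2A1, a glucose carrier (4.92-fold), and BNIP3 (3.57-fold), the epithelial list 6 of 8 lower (−1.94) and the mesenchymal list 8 of 18 lower (−0.64), so genes of other cell types were lower together. BNIP3, ENO1, LDHA and HK2 were lower at E28 in all 6 other classes too, so their difference is not specific to endothelium-like cells. PPBP, a platelet gene (at least 43.5-fold), and ISM2 (at least 33.7-fold) were lower, but PPBP turned to a log2 ratio of 6.43 with doublets removed at the expected rate and ISM2 to 0.09 with the libraries clustered together. From E28 to E31 (301 cells) EPHA4 (9.67-fold) and TCF21 (6.21-fold) were higher and NKAIN4 (4.47-fold) and TMEM255B (6.82-fold, as in all classes measured) lower. No cell cycle gene of 18 was apart (0.22). Genes of coelomic, kidney and mesenchymal cells, picked after their values were seen, were higher with TCF21: ALDH1A2 (5.55-fold), COL1A1 (5.496-fold), WT1 (4.85-fold), KRT18 (3.96-fold) and LHX1 (2.59-fold). TCF21 is therefore not read as a difference of endothelial cells. From E31 to E37 (194 cells, clusters 0 and 25) NTS (34.0-fold, 20.2 to 61.6) and IGFBP5 (11.1-fold) were higher and ESM1, a gene of angiogenic tip cells (17.99-fold), and HOXD1 (38.7-fold, 6.75 to 1550.4, 1 UMI) lower, and the HOX list had HOXA10 higher and 8 lower of 24 (−0.60). ESM1 stood at −0.25 in place of −4.14 at a Leiden resolution of 2, EPHA4 at 1.96 in place of 3.15 with called doublets kept, and TCF21 at 1.05 in place of 2.58 and the E28 over E24 epithelial median at −0.92 with doublets removed at the expected rate.

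Neural-crest-like or glia-like cells at E28 (118 cells) had the neuronal tubulin TUBB3 130.3-fold above E24 (138 cells, 72.6 to 262), while the caudal factor CDX1 (at least 56.7-fold) and ZIC5 (at least 24.3-fold) were lower. The mesenchymal list had 11 higher and LUM, SNAI2 and COL6A3 lower of 18 (median 1.12), and the hypoxia and glycolysis list NDRG1 higher and 8 lower of 10 (−1.76), among them SLC2A1 (5.09-fold) and ENO1 (3.68-fold). Genes of other cell types, picked after their values were seen, were higher with the mesenchymal list: NR0B1 (29.98-fold, 9.94 to 148, 3 UMIs) and WT1 (10.4-fold, 2.54 to 91.3, 2 UMIs). TUBB3 stood at a log2 ratio of 4.79 in place of 6.96 at 1000 genes per cell. At E31 (196 cells) against E28, ASS1 (5.64-fold) and NTRK2 (3.34-fold, a log2 ratio of 0.84 in place of 1.71 with called doublets kept) were higher and FOS (12.6-fold) and EGR1 (7.55-fold) lower. At E37 (409 cells, clusters 1 and 20) against E31, GRIK1 (at least 100.7-fold) and FOS (23.1-fold) were higher and LIN28A (33.6-fold) and STMN2 (24.3-fold) lower, and 9 of 20 mesenchymal genes were higher (0.63), among them COL5A1 (4.23-fold). STMN2 turned to 1.01 with the libraries clustered together. LIN28A was lower at E37 in every other class that measured it too, so it is not specific to glia-like cells.

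Smooth-muscle-like or pericyte-like cells at E28 (186 cells, cluster 17) and E24 (673 cells, cluster 2) differed on several lists. KRT19 (376-fold, 161 to 1157) and LUM (186-fold, 122 to 301.1) were lower at E28 and CYP1B1 (167-fold, 92.2 to 336) and TNMD (201-fold, 54.2 to 1679.6, 2 UMIs) higher. LUM was lower at E28 in every other class that measured it too. KRT19 is a fixed marker of coelomic epithelium, and the epithelial list was lower with it. The differences of this class between E28 and E24 are therefore not read as those of smooth muscle alone. The epithelial list had 7 of 10 lower (median −3.60, or −3.77 with genes at 0 UMIs set to their bounds), the cell cycle list 13 of 18 lower (−1.95) and the HOX list 16 higher and HOXA10, HOXA11 and HOXA13 lower of 28 (1.14). The epithelial median was −4.19 with called doublets kept, and CYP1B1 stood at a log2 ratio of 8.36 in place of 7.32 with means of CPM per cell. At E31 (217 cells) against E28, the natriuretic peptide gene NPPB (8.04-fold) and TYW3 (3.74-fold) were higher and FOS (5.86-fold) and EGR1 (4.85-fold) lower, and UBE2C, TYMS, AURKB, MKI67 and CDK1 were lower of 16 cell cycle genes (−0.80), a median that turned to 0.36 with called doublets kept. At E37 (243 cells) against E31, IGFBP7 (44.5-fold, 21.3 to 112) and CRIP1 (60.3-fold, 20.3 to 295, 3 UMIs) were higher and NPPB (207-fold, 36.7 to 8206, 1 UMI) and NR0B1 (34.6-fold) lower, with UBE2C, TOP2A, AURKB, MKI67 and CDK1 higher of 18 cell cycle genes (0.51, or 1.16 at 1000 genes per cell).

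Somite-like or sclerotome-like cells at E28 (314 cells, cluster 16) against E24 (1364 cells, clusters 8 and 11) had higher BCL11A (239-fold, 80.6 to 1166, 3 UMIs) and lower RIPPLY1, a gene of forming somites (896-fold, 161 to 35394, 1 UMI), and LUM (119-fold). The HOX list had 11 higher and HOXB1 and HOXB4 lower of 30 (median 0.56), with HOXC10 (28.01-fold) and HOXD10 (13.6-fold) foremost, and UBE2C was higher of 18 cell cycle genes (0.42). Genes of coelomic and kidney cells, picked after their values were seen, were higher too: WT1 (84.96-fold, 57.9 to 130), TCF21 (26.7-fold), GATA3 (17.1-fold), EMX2 (12.1-fold) and PAX8 (9.20-fold). The differences of this class are therefore not read as those of somite cells alone. BCL11A stood at a log2 ratio of 6.61 in place of 7.68 with the libraries clustered together, RIPPLY1 at −8.52 in place of −9.22 with called doublets kept and LUM at −5.95 in place of −6.85 at a Leiden resolution of 2. That cell cycle median turned to −2.42 at a Leiden resolution of 2 and to −0.61 with the libraries clustered together. At E31 (395 cells, cluster 2) against E28, STYXL1 (7.27-fold) and PMP22 (5.54-fold) were higher and EGR1 (14.5-fold) and FOS (9.28-fold) lower, with 10 of 18 cell cycle genes lower (−1.05, −1.44 to 0.43 over members). That median turned to 1.24 at a resolution of 2. PMP22 turned to −0.19 with called doublets kept.

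Macrophage-like cells at E37 (93 cells) against E31 (52 cells) had lower division genes, with 7 of 18 cell cycle genes lower (median −0.94), among them CCNB2 (3.09-fold) and CDK1 (2.63-fold). CRABP2 (6.29-fold) and H1-3 (3.56-fold) were lower, and PPBP (at least 151-fold) and AZU1, a neutrophil granule gene (143-fold, 48.8 to 698, 3 UMIs), higher. AZU1 turned to a log2 ratio of −2.73 and PPBP stood at 1.66 in place of 9.82 at a Leiden resolution of 2. Here and in every comparison of named classes, the fold ratios relate class totals and carry no test.

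The stress list, mostly immediate early genes, differed between successive libraries in the same direction across classes. The stress list median was below 0 in all 9 classes compared between E31 and E28, from −2.13 in coelomic-epithelium-like cells to −0.71 in endothelium-like cells, and above 0 in all 7 classes compared between E37 and E31, from 0.55 in erythroid-like to 3.14 in nephric-epithelium-like cells. Between E28 and E24 it was 2.14 in intermediate-mesoderm-like, 2.66 in nephric-epithelium-like, 1.15 in endothelium-like, 2.15 in glia-like, 1.05 in erythroid-like, 0.45 in smooth-muscle-like and 3.02 in somite-like cells. FOS in intermediate-mesoderm-like cells stood at 18.3, 299, 71.4 and 449 CPM at E24, E28, E31 and E37. In the E31 over E28 pair the medians of the glia-like (4 of 8 genes lower), erythroid-like (4 of 7), smooth-muscle-like (4 of 10), somite-like (8 of 10) and endothelium-like cells (4 of 10) were −1.22, −1.13, −0.96, −1.38 and −0.71, and in the E37 over E31 pair those of endothelium-like, glia-like, smooth-muscle-like and macrophage-like cells were 1.36, 2.01, 1.35 and 0.74. No stress median turned under an alternative. Those at E31 over E28 that shifted by over 1.5 times were erythroid-like (−0.44 with means of CPM per cell), smooth-muscle-like (−1.59 with called doublets kept) and somite-like (−2.26 at a Leiden resolution of 2), and at E28 over E24 glia-like (2.90 with called doublets kept and 2.77 at 1000 genes per cell).

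**Figure D4:**
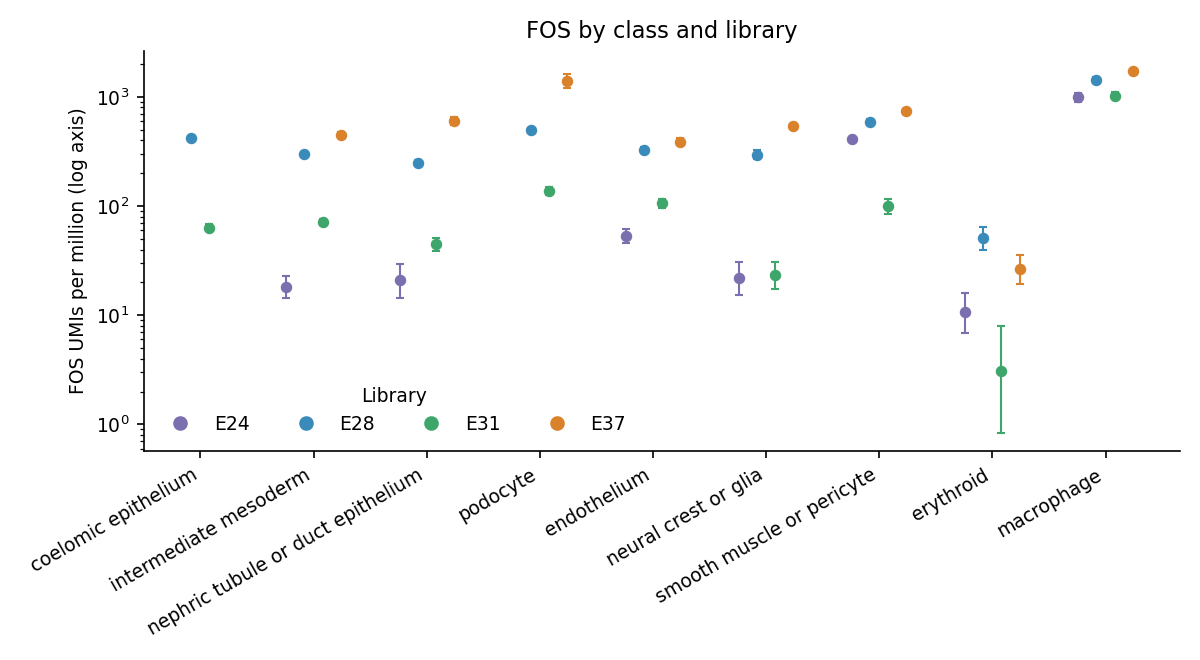
Level of the immediate early gene FOS (vertical axis, CPM of the class total, log scale) by class in the E24, E28, E31 and E37 libraries, with exact 95% Poisson intervals as bars. In coelomic-epithelium-like cells FOS stands at 423 CPM at E28 and 63.4 at E31, and in intermediate-mesoderm-like cells at 299 and 71.4.

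Erythroid-like cells, named without globins, held embryonic globins at every stage. HBE1, the embryonic beta-like globin, made up 49.4%, 54.1%, 53.6% and 64.1% of the UMIs of named globins at E24, E28, E31 and E37, and HBZ, the embryonic alpha-like globin, 50.2%, 45.2%, 45.9% and 34.9%. HBM made up 0.352%, 0.639%, 0.414% and 0.953%. The adult beta globin HBB had 51, 59, 45 and 85 UMIs. Named globins took 23.4%, 35.2%, 36.0% and 41.0% of all UMIs in erythroid-like cells and 0.0148%, 0.0163%, 0.0290% and 0.0121% in endothelium-like cells, a measure of free globin RNA. The loci LOC102143165 and LOC102136846, which the sources used here do not resolve to a globin symbol, took a further 24.4% and 16.2% of all globin UMIs at E24 and 16.2% and 21.9% at E37, so the shares above hold for named globins only.

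Outside the globins, erythroid-like cells numbered 99, 48, 48 and 111, with E28 and E31 below the 50 cells asked of other shared classes. Division genes were lower at E37 than at E31, with 10 of 17 cell cycle genes lower (median −1.02), among them CDK1 (4.47-fold, 3.02 to 6.79) and PCNA (2.84-fold), and HMGA1 was 3.11-fold lower. GLRX (59.2-fold, 10.3 to 2370.2, 1 UMI) and CA1, a red cell carbonic anhydrase (8.51-fold), were higher at E37, and PGK1 was lower (2.37-fold) among 6 hypoxia and glycolysis genes (−0.47). ZC3H3 (38.2-fold) and S100A6 (12.1-fold) were higher and LUM (84.8-fold, 14.97 to 3376, 1 UMI) and RHOBTB1 (17.3-fold, 5.72 to 85.6, 3 UMIs) lower at E28 than at E24. DDIT4 (5.48-fold) and MAP1B (3.45-fold) were higher and ZC3H3 (16.5-fold) and GLRX (45.6-fold, 7.82 to 1838, 1 UMI) lower at E31 than at E28. With globins taking so large a share, TMM factors shifted these comparisons by 0.36, 0.13 and 0.38. LUM stood at a log2 ratio of −3.89 in place of −5.83 and CA1 at 4.33 in place of 3.03 with doublets removed at the expected rate.

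Germ-cell-like cells were few and formed no cluster. With UMIs of at least 3 of 11 markers there were 22 at E24 (0.207%, 0.130% to 0.313%), 7 at E28 (0.141%), 10 at E31 (0.151%) and 4 at E37 (0.0758%). At 4, 5 or 6 markers the counts were 11, 4, 5 and 4 at each of these thresholds. In those cells the pluripotency factor POU5F1 stood at 1404, 1781, 1102 and 1950.2 CPM, NANOG at 470.3, 394.5, 513 and 468 and SOX17, a regulator of primate germ cell fate, at 415, 329, 298 and 212. DDX4 had 1, 0, 0 and 2 UMIs and DAZL, a gene of later germ cells, had 0 in all 4 libraries. These genes are among the markers that select the cells, so their levels describe the selection. At 4 or more markers 10 of the 11 cells at E24 lay in cluster 28, whose other cells were named erythroid-like, all 5 at E31 in cluster 16 and all 4 at E37 in cluster 22.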

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

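The following differences between classes stood out because a fixed gene list was higher in some class and lower in another over the same pair of stages, and the difference between classes was not tested. Of the tests weighed further below, all were chosen after the result was seen except the depth test of the genes shifted in every class, which was chosen before.

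For the epithelial list at E28 over E24, the median log2 ratio was 0.62 in intermediate-mesoderm-like and −3.60 in smooth-muscle-like cells, 4.21 apart, not tested. For the cell cycle list over the same stages it was 0.42 in somite-like and −1.95 in smooth-muscle-like cells, 2.37 apart, not tested. KRT19, a marker of coelomic epithelium, was also lower at E28 in the smooth-muscle-like cells. Neither of their values is therefore read as that of smooth muscle alone. The somite-like value turned to −2.42 at Leiden resolution 2 and to −0.61 with the libraries clustered together, so the opposite directions depend on the clustering. At E31 over E28 the cell cycle median was 0.22 in endothelium-like and −0.80 in smooth-muscle-like cells, 1.02 apart, not tested. The smooth-muscle-like value turned to 0.36 with called doublets kept, which ends the contrast. At E37 over E31 the WNT median was 1.28 in nephric-epithelium-like and −0.50 in intermediate-mesoderm-like cells, 1.78 apart, not tested. The nephric-epithelium-like value was 0.27 at Leiden resolution 2, which narrows the contrast. The cell cycle median there was 0.51 in smooth-muscle-like and −1.02 in erythroid-like cells, 1.53 apart, not tested. The erythroid-like value was −0.64 with TMM factors and the smooth-muscle-like value 0.19 with called doublets kept. The hypoxia and glycolysis median was 0.42 in nephric-epithelium-like and −0.47 in erythroid-like cells, 0.89 apart, not tested. The median of all measured genes in erythroid-like cells was −0.40, and with TMM factors the hypoxia and glycolysis value was −0.09, so it stands near the level of that class as a whole. The HOX median was 0.38 in intermediate-mesoderm-like and −0.60 in endothelium-like cells, 0.98 apart, not tested.

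Dissociation stress genes were lower at E31 than at E28. A difference in handling or in embryo that reached every class of a library predicts a lower median in all classes, and 9 of 9 medians were below 0, but this count is the pattern itself and a stage effect in every class predicts the same, so it decides nothing. Free RNA from lysed cells predicts equal stress UMIs per cell, but coelomic-epithelium-like cells held 28.7 (28.3 to 29.1) and nephric-epithelium-like cells 17.1 (16.7 to 17.6) at E28, 1.67 times as many, which argues against free RNA as the whole cause. Handling, embryo and developmental stage cannot be told apart with 1 library per stage.

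Genes shifted the same way in every class between E28 and E31 were also weighed. Free RNA would weigh more in shallow cells, so their level should be higher there by up to the ratio of depths, 1.76 at E28 and 1.97 at E31. Across 17 genes the median ratio of levels in shallow over deep intermediate-mesoderm-like cells was 1.10 (1.003 to 1.27), which argues against free RNA as the whole cause. A difference between embryos, animals or library preparations cannot be told apart from stage, with 1 library per stage.

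Nephrogenic mesoderm genes were lower in gonadal-somatic-like cells at E37 than in coelomic-epithelium-like cells at E31. Free RNA in the E31 cells predicts levels like those of endothelium-like cells. Of the 6 lower members, LHX1, EYA1, PAX8 and OSR1 held more UMIs per cell in coelomic-epithelium-like than in endothelium-like cells (0.265 against 0.163, 0.227 against 0.116, 0.489 against 0.113 and 0.349 against 0.0133). SALL1 (0.153 against 0.126) had overlapping intervals, and GATA3 (0.799 against 1.38) stood lower. Free RNA is therefore unlikely as the whole cause for the former 4, a group formed after these values were seen. For SALL1 and GATA3 it cannot be told apart. Doublets with nephric cells in the E31 class cannot be told apart: the median was −3.70 after doublets were removed at the expected rate, against −2.62 (−4.55 to 0.19), but its interval holds 0 and the E31 class shrank to 7.06% of cells. Whether other E37 cells share the difference cannot be told. The median was −2.97 (−5.66 to −0.32 over 5 members) in endothelium-like cells at E37 over E31, whose E31 level stood for free RNA above. Stage and dissection also differ and were not tested.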

How the results depend on the processing

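Of 379 values of the main results under alternatives, 313 stayed within their main interval (counts, within 1.5 times), 65 moved and 1 reversed; of 2059 values of named genes and other lists, 1905 kept, 131 moved and 23 reversed. A sign change counted as reversed only where the main interval excluded 0. A further 57 log2 values changed sign from a main value whose interval held 0, of which 50 stayed within that interval and 7 moved: KRT18 (0.23) and the cell cycle median (−2.45) in coelomic-epithelium-like cells (E31 over E28, doublets removed at the expected rate), and the cell cycle median in somite-like cells (1.24, E31 over E28, Leiden resolution 2) and in intermediate-mesoderm-like cells at E37 over E31 (0.30 at 1000 genes per cell, 0.71 with called doublets kept, 0.44 with outcome genes kept and 0.42 with doublets removed at the expected rate). All 14 values of the main results under means of CPM per cell and 41 of 42 under TMM factors were kept, and of 293 values of named genes and other lists 5 and 6 moved under these. No paired analysis was possible because each stage has 1 library. The E24 barcodes by suffix were not run, as there is a single suffix, and neither was the mitochondrial limit, as no mitochondrial gene is named. Leiden resolution 2 gave no coelomic class at E31, so 28 values could not be computed, and clustering the libraries together left 15 without a gonadal class to compare. Cluster 19 was computed under the main settings only. Removing doublets at the expected rate was chosen after seeing the data. The 12 and 18 GATA4 UMIs of the coelomic class limit its ratio by depth. For every value below the cause was not tested.

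At Leiden resolution 2 the shares were 7.31% for coelomic-epithelium-like cells at E28, 4.89% for gonadal-somatic-like cells, 16.8% and 11.3% for intermediate-mesoderm-like cells at E28 and E31, 8.94% for podocyte-like cells at E31 and 67.4% unnamed at E37. With the libraries clustered together they were 5.96% and 6.28% for coelomic-epithelium-like cells at E28 and E31, 0.114% gonadal, 19.3% intermediate mesoderm at E31, 7.90% podocyte at E31 and 74.2% unnamed at E37. With outcome genes kept they were 12.1% coelomic at E31, 4.98% gonadal, 17.4% and 12.5% intermediate mesoderm at E28 and E31 and 65.4% unnamed at E37. With doublets removed at the expected rate they were 7.06% coelomic at E31, 11.01% gonadal, 13.5% intermediate mesoderm at E31, 9.75% podocyte at E31 and 62.2% unnamed at E37. At 1000 genes per cell they were 13.7% intermediate mesoderm and 9.71% podocyte at E31 and 62.5% unnamed at E37, and HBE1 was 64.2% of HBE1 plus HBZ at E37. With called doublets kept they were 11.3% intermediate mesoderm and 11.1% podocyte at E31 and 65.7% unnamed at E37.

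With 2 germ cell markers the counts were 292, 68, 80 and 38, and with 4 they were 11, 4 and 5 at E24, E28 and E31. Not thinned, PAX8 was found in 46.5% and 30.02% of coelomic-epithelium-like cells at E28 and E31, and LHX9 in 6.21% at E31 and in 60.5% of the gonadal class. Thinned to 4000 UMIs these were 25.4%, 14.5%, 2.31% and 45.1%.

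In coelomic-epithelium-like cells at E31 over E28, mesenchymal members lower were 2 at 1000 genes per cell and with called doublets kept, 3 with the libraries clustered together and 3 at 1.5-fold, with 1 higher at 1.5-fold. Epithelial members lower were 1 at 1.5-fold. Nephrogenic members lower were 0 with the libraries clustered together, with doublets removed at the expected rate and at 50 UMIs, and 2 at 1.5-fold; those higher were 2 with outcome genes kept, 2 at 1.5-fold, 1 with doublets removed at the expected rate and 1 with TMM factors. In the gonadal class over the E31 epithelium, outcome genes kept gave a reversed mesenchymal median of −0.16 with 3 higher and 3 lower, 1 nephrogenic and 2 HOX members higher; doublet removal at the expected rate gave 1 epithelial member higher. In intermediate-mesoderm-like cells at E28 over E24, outcome genes kept gave a BMP median of 0.30 with 4 higher.

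These log2 ratios and list medians also reversed. With outcome genes kept: in the gonadal comparison BMP −0.0286, cell cycle −0.72 and EMX2 0.49, and in intermediate-mesoderm-like cells cell cycle −0.22 (E28 over E24) and −0.19 (E31 over E28) and SST −0.44. At Leiden resolution 2: cell cycle −0.0367 in intermediate-mesoderm-like and −2.42 in somite-like cells (E28 over E24), AZU1 −2.73 in macrophage-like cells and PMP22 −1.30 in somite-like cells. With called doublets kept: cell cycle −0.62 and SST −1.97 in intermediate-mesoderm-like cells, cell cycle 0.36 in smooth-muscle-like cells and PMP22 −0.19 in somite-like cells (all E31 over E28). At 1000 genes per cell: cell cycle −0.27 and SST −1.45 in intermediate-mesoderm-like cells (E31 over E28). With the libraries clustered together: cell cycle −0.61 in somite-like cells and ISM2 0.0901 in endothelium-like cells (E28 over E24), and STMN2 1.01 in glia-like cells (E37 over E31). With doublets removed at the expected rate: ALDH1A2 0.11 in coelomic-epithelium-like cells, cell cycle −0.37 and SST −1.95 in intermediate-mesoderm-like cells (all E31 over E28), and PPBP 6.43 in endothelium-like cells (E28 over E24).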

Other observations

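The cluster highest in NR0B1, a nuclear receptor of the adrenal and gonad, did not meet the rule for an adrenal or gonadal name in any library. NR0B1 was at 269 CPM in cluster 12 at E24 (323 cells), 315 in cluster 11 at E28 (223 cells), 449.8 in cluster 11 at E31 (356 cells) and 116 in cluster 9 at E37 (280 cells), against library levels of 31.5, 58.0, 89.4 and 38.7. Named classes held it too, with 228 CPM in coelomic-epithelium-like cells at E31 and 88.7 in intermediate-mesoderm-like cells at E37. The cholesterol carrier STAR in the same clusters stood at 10.7, 45.9, 30.2 and 88.7 CPM, and FDX1, an electron donor in steroid synthesis, at 159.9 CPM in cluster 9 at E37 against 107 in the library. Other genes of steroid synthesis and its control had few UMIs, which, as the annotation used is not given in the sources used here, are not read as absence: CYP17A1 had 21, 11, 14 and 9 UMIs per library, HSD3B2 0, 1, 0 and 3, and the receptor MC2R 0 in all 4. MRAP, its partner, had 2, 10, 0 and 16 UMIs, 11 of the 16 at E37 in cluster 9.

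Among genes measured in 5 or more classes, some were at least 2-fold apart in the same direction in every class with the gene measured: 29 of 8669 between E28 and E24, 17 of 9396 between E31 and E28 and 16 of 7389 between E37 and E31. The largest median ratios were for LUM (84.8-fold lower) and CALB1 (36.1-fold higher) at E28, STYXL1 (7.59-fold higher) and LRRC8B (6.95-fold lower) at E31, and LIN28A (33.6-fold lower) and DCN (27.97-fold higher) at E37. IFI27 was 4.37-fold higher and TXNIP 3.21-fold lower at E31, and NFIA 5.74-fold higher and ENO3 5.99-fold lower at E37. Over whole libraries LIN28A stood at 194, 48.2, 59.8 and 2.82 CPM, NFIA at 0.937, 6.43, 5.30 and 123 CPM and STYXL1 at 10.3, 3.63, 17.8 and 4.20 CPM at E24, E28, E31 and E37.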
